A study of Mus musculus with 4 samples.

How the data were processed

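Total RNA came from subcutaneous white adipose tissue of wild-type (WT) and fat-specific mitochondrial ferritin transgenic (FtMT-Adip) mice, with 2 samples each. It was labelled with biotin and hybridised to Illumina BeadChips, which carry beads coated with gene-specific probes, per the labels' protocols. Per the labels, RNA was extracted with Trizol, treated with DNase I and checked on a Bioanalyzer. Those labels name the MouseRef-8 v2 chip, whereas the tables hold 45281 probes per array, more than that chip carries, so the chip type is not settled here. Replicate numbers 1 and 2 come from the sample titles, which do not say whether an array holds 1 mouse or a pool.

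Of the files the authors deposited, 1 table holds non-normalized intensity values on a linear scale, named as such in its title, with background not subtracted (lowest signal 91.3 to 93.1 per array). The other deposited table holds intensity values that its title calls normalized, with a method not given in the sources used here. Its medians per array were 3.48, 3.54, 3.55 and 3.65, and within an array its values ranked differently from the non-normalized ones (Spearman rank correlation across probes 0.908 to 0.911). The value table of the series was identical to it (largest difference 0), on a linear scale, not centred on 0. Per the file headers, the deposited normalized table also gives a ratio of the FtMT-Adip mean over the WT mean and a p-value for each probe. The deposited p-value was recomputed as an equal-variance test on the linear normalized values, with a largest difference of 2.8e-13. Software for scanning and summarising beads was not given in the sources used here.

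The main values were computed from the non-normalized intensity with limma 3.58.1 in R 4.3.3. Background was corrected with normexp (offset 50), arrays were quantile normalized and values were put on the log2 scale. Detection p-values, which the planned neqc normalization needs, were not among the columns used here, so the stated fallback of normexp and quantile normalization was taken. In place of the detection p, each probe was ranked on its array against 1479 probes for olfactory and vomeronasal receptors, genes of the nose taken as not expressed in fat. This substitute was chosen after the tables were seen. A probe was tested when this empirical probability was under 0.05 on at least 2 of the 4 arrays, which left 20797 probes. The 95th percentile of the receptor probes was 119.6 to 123.5, and 43.5% to 45.1% of probes exceeded it on an array. Total signal per array was 15086032 and 14375281 in WT, and 14143397 and 14820135 in FtMT-Adip. Across tested probes the Pearson correlation was 0.988 between the WT arrays, 0.989 between the FtMT-Adip arrays and 0.959 to 0.974 between groups, where probes are not independent replicates.

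Probe names are those of the tables, which hold older symbols. They were matched to mouse symbols of the RefSeq annotation of GRCm38.p6, by symbol for 22864 probes and by a synonym belonging to a single gene for 11917. Another 10473 probes kept the name in the table, and 27 whose names had turned into dates were left unnamed. A genome build is not named in the tables, so no coordinates are given. A gene with several tested probes is represented by the probe of highest mean signal, so its other probes need not share its call. For Fdxr, Hspd1, Pkm, Echs1, Clstn3, Otop1, Fdps and Mmp13, 1 of 2 tested probes was called in the direction given. The same held for 1 of 3 probes of Acot2 and for 2 of 3 of Srxn1 and Cpa3.

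FtMT-Adip was compared with WT in a linear model (lmFit and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all tested probes at 0.05. Errors given as SE are the moderated standard errors of the log2 change, with 2 arrays per group. The prior had 6.86 degrees of freedom. No scan date or slide is given, so batches could not be examined. Before the data were examined, 25 gene lists and 12 cell type marker lists were fixed, holding 946 entries of which 927 were on the array. Each list with at least 5 tested genes was tested with camera (preset correlation 0.01), with adjustment over the 37 lists. Alternatives were camera with an estimated correlation and fry. With an estimated correlation, camera relies on the few residual degrees of freedom left by 2 arrays per group, so a list could hardly pass. Counts adjusted over the list alone use the members' p-values only. Where all arrays of a group were below background, a bound was set from the lowest detected signal per array.

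The genes named were chosen by a rule fixed before the data were examined. It takes Ftmt, the 10 largest rises and the 10 largest falls among called probes with a gene symbol whose arrays do not overlap, from each list up to 4 called members with the largest change or otherwise those with the smallest unadjusted p, and Adipoq, Lep, Ucp1, Pparg and Gdf15. Other list members named in the text (such as Gpt2, Vldlr, Phgdh, Plin2, Hfe, Heph, Aco1, Tfr2, Alad, Hp, Sfrp5, Saa3, Itih4, Cxcl14, Ccn2, Col4a1 and Col4a2, and Tnnc2, Cidea and Cox7a1 per array) were chosen after their values were seen.

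The fit and the list test were tested on simulated data, 20797 probes on the log2 scale on 2 arrays per group, with variances drawn from the prior fitted to the real ones. Of 100 probes changed 2-fold, 77% were called with the right sign, and of 100 changed 4-fold, 100%. Of 185 calls 7 were of unchanged probes, and of the 37 lists the changed one was called and 0 others. Probes were simulated as independent, whereas estimated correlations in the real lists reached 0.85 (skeletal muscle). The simulation therefore does not test false list calls among correlated genes. Alternatives covered background correction, normalization, the authors' normalized values, the filter on dim probes, the variance model, a replicate block and leaving out each array in turn. With 1 array left in a group, limma assumes that it varies like the other group.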

Results

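Gene expression was profiled in subcutaneous white adipose tissue of C57BL/6 mice, 8 to 12 weeks old, that had been fed a high-fat diet with doxycycline for 3 weeks. The transgenic animals, FtMT-Adip, carried a fat-specific transgene for mitochondrial ferritin, a protein that stores iron inside mitochondria. The other animals were wild-type (WT) and received the same diet. Each group was represented by 2 arrays, which the sample titles number as replicates. The titles do not say whether an array holds an individual mouse or a pool. Every array reported 45281 probes, with a median signal between 116.5 and 119. Between 19717 and 20427 probes per array lay above the background of olfactory and vomeronasal receptor probes. The number of arrays limits the precision of every comparison below.

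The design asks how an overexpression of mitochondrial ferritin in fat alters expression in the tissue. The probe for the mouse gene Ftmt (ILMN_2705758) gave raw signals of 102.1 and 110.6 in WT and 104.9 and 106.8 in FtMT-Adip, and was not above background on any array. Whether this probe matches the transcript of the transgene is not known, so its signal does not check the labels.

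By camera with a preset correlation, targets of the stress factor ATF4 and transcripts of macrophages and the interferon response were higher in FtMT-Adip. Transcripts of adipocytes, their secreted proteins and endothelial cells were lower by the same test. With an estimated correlation, a test of little power at 2 arrays per group, 0 of the 37 lists passed (smallest adjusted p = 0.296). Of 20797 tested probes, 1548 (7.44%) passed a Benjamini-Hochberg threshold of 0.05 in limma, 682 higher and 866 lower in FtMT-Adip. More than a 2-fold change was found for 238 of the higher and 270 of the lower probes. The called probes belonged to 1256 distinct genes, and 0 genes had probes called in both directions. At an unadjusted p under 0.05 there were 4449 probes. The arrays of both groups did not overlap for 51.5% of tested probes, against 33.3% by chance. The count of called probes fell to 652 without FtMT-Adip 1 and to 927 without WT 1. In the matrix that the authors normalized it was 695.

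**Figure D1:**
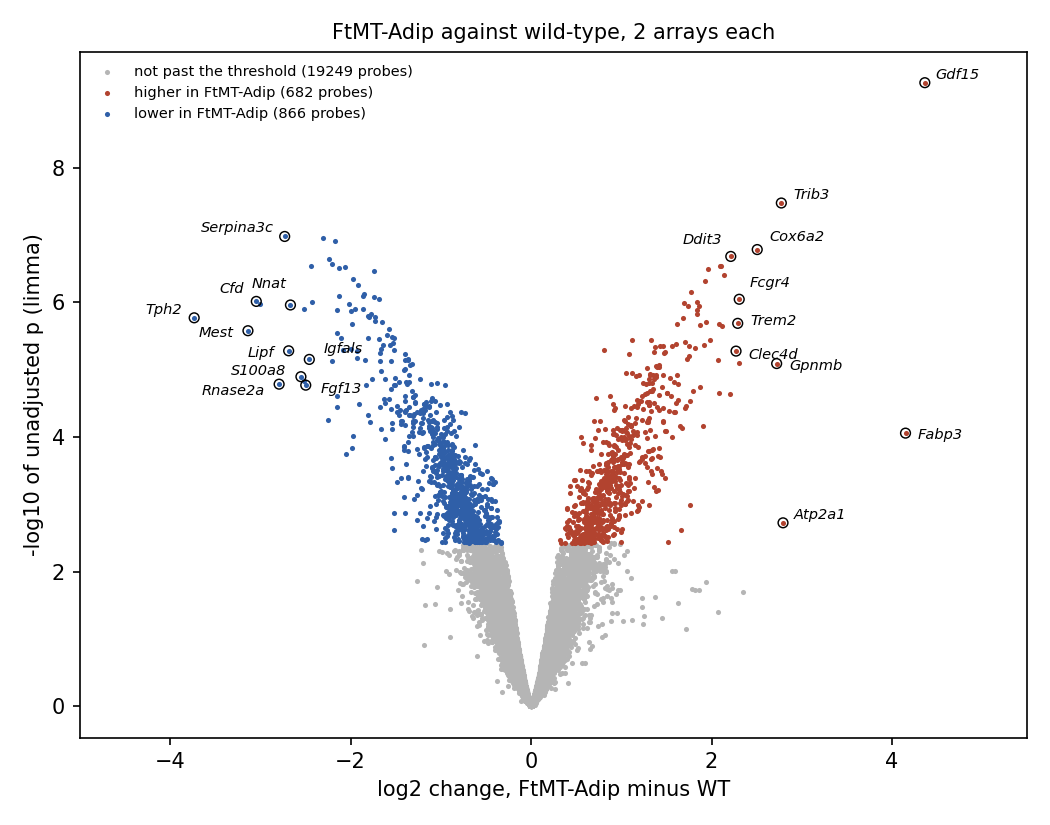
Each point is a probe, with the log2 change (FtMT-Adip minus WT, 2 arrays per group) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis; red points were called higher, blue points lower, and grey points neither. Gdf15 stands farthest to the upper right (log2 change 4.36), and the circled genes are the 10 largest rises and 10 largest falls.

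The largest rise was in Gdf15, a secreted stress cytokine (ILMN_2735350), whose mean log2 signal was 6.53 ± 0.01 (SD, n = 2) in WT and 10.89 ± 0.14 (SD, n = 2) in FtMT-Adip. This is a 20.6-fold difference (log2 change 4.36, SE 0.154, adjusted p = 1.13e-05). Fabp3, the fatty acid-binding protein of heart and muscle (ILMN_2887630), was 17.7-fold higher (log2 change 4.15, SE 0.612, adjusted p = 0.00526). Its signal was above background on 1 of the 2 WT arrays, with 435.7 in WT 1 and 113.3 in WT 2, against 2676 and 3001 in FtMT-Adip, and the log2 change was 2.90 without WT 2 and 5.40 without WT 1, so the size of the rise is uncertain. Cox6a2, the cytochrome c oxidase subunit of heart and skeletal muscle (ILMN_2629581), was 5.68-fold higher (log2 change 2.51, SE 0.171, adjusted p = 0.000441). The stress-induced pseudokinase gene Trib3 rose 6.83-fold (ILMN_1225528; SE of log2 0.157, adjusted p = 0.000347) and the transcription factor gene Ddit3, also called CHOP, 4.64-fold (ILMN_2652909; SE of log2 0.155, adjusted p = 0.000441). Among the other rises of the 10 largest, Gpnmb, a glycoprotein of lipid-laden macrophages, was 6.59-fold higher (adjusted p = 0.00153), Trem2, a macrophage lipid receptor, 4.89-fold (adjusted p = 0.000787), the Fc receptor gene Fcgr4, listed as FCRL3, 4.95-fold (adjusted p = 0.000657) and the lectin gene Clec4d, listed as CLECSF8, 4.83-fold (adjusted p = 0.00123). Atp2a1, the calcium pump of fast muscle, was 6.92-fold higher (log2 change 2.79, SE 0.639, adjusted p = 0.0326), with most of its signal in a single array. Raw signals were 123 and 154.9 in WT, 1498 in FtMT-Adip 1 and 321.1 in FtMT-Adip 2, the log2 change was 1.51 without FtMT-Adip 1 and 4.07 without FtMT-Adip 2, and the call ended without WT 1, without WT 2 or without a variance trend.

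The largest falls included several products of adipocytes. Cfd, the complement factor also known as adipsin (ILMN_2835423), went from a mean log2 signal of 14.27 ± 0.60 (SD, n = 2) to 11.23 ± 0.27 (SD, n = 2), an 8.25-fold difference (log2 change -3.04, SE 0.256, adjusted p = 0.000657). Mest, an imprinted gene linked to fat expansion (ILMN_2846904), was 8.79-fold lower (log2 change -3.14, SE 0.298, adjusted p = 0.000912), and the imprinted gene Nnat 6.35-fold lower (adjusted p = 0.000657). Serpina3c, a protease inhibitor, was 6.63-fold lower (log2 change -2.73, SE 0.177, adjusted p = 0.000441). Tph2, which encodes a tryptophan hydroxylase (ILMN_2460179), showed the largest fall, 13.3-fold (log2 change -3.73, SE 0.336, adjusted p = 0.000718). Also lower were Lipf (6.43-fold, adjusted p = 0.00123), the ribonuclease gene Rnase2a, listed as EAR11 (6.92-fold, adjusted p = 0.00222, above background on 1 of the 2 FtMT-Adip arrays), the neutrophil alarmin gene S100a8 (5.85-fold, adjusted p = 0.00198), Fgf13 (5.64-fold, adjusted p = 0.00222) and Igfals (5.49-fold, adjusted p = 0.00142). For Fgf13, 2 of the 3 tested probes were called. All of these falls stayed called when any 1 array was left out.

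Genes of iron handling changed in both directions. Of 37 tested members 3 were higher and 6 lower (4 and 7 when adjusted over the list alone), and the list as a whole did not shift (mean log2 change 0.02, adjusted p = 0.921 by camera). The ferritin light chain gene Ftl1 was 2.16-fold higher (log2 change 1.11, SE 0.126, adjusted p = 0.00194), with the caution that near-identical copies of ferritin genes can share a probe. The transferrin receptor gene Tfrc (1.11, SE 0.241) and the endosomal metal transporter gene Slc11a1 (1.08, SE 0.196) were also higher on the log2 scale. Macrophage markers rose in the same arrays (mean 1.12), and whole tissue does not show which cells raised these genes. Trf, which encodes transferrin, was 2.27-fold lower (log2 change -1.18, SE 0.153, adjusted p = 0.00322). The other lower members were Hfe (-0.92), Heph (-0.87), Aco1 (-0.68), Tfr2 (-0.67) and Alad (-0.61). Leaving out WT 1 left 1 higher and 2 lower members, and leaving out FtMT-Adip 1 left 1 higher and 3 lower. The lower count was 3 without WT 2 and 2 without FtMT-Adip 2. The call of Tfrc ended without WT 1, FtMT-Adip 1 or FtMT-Adip 2 (log2 change 0.72 without WT 1) and that of Slc11a1 without WT 1 or FtMT-Adip 1 (0.86 to 1.31 over the 4 left-out arrays). Tfrc was also not called in the authors' normalized values.

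Iron-dependent and respiratory chain genes showed few calls. In iron-sulfur cluster assembly 2 of 22 tested genes were higher, the chaperone gene Hspa9 (log2 change 0.90, SE 0.161) and the ferredoxin reductase gene Fdxr (0.57, SE 0.145), and the list did not pass (mean 0.11, adjusted p = 0.209). Among iron-sulfur and mitochondrial haem proteins 1 of 22 was lower, Cisd1, which encodes an iron-sulfur protein of the outer mitochondrial membrane (-0.74, SE 0.190; list mean -0.05, adjusted p = 0.528), and 0 were called when adjusted over the list alone. In complex I, 0 of 34 tested genes were called, and the mean was -0.03 while the median was 0.00 (adjusted p = 0.691). The smallest unadjusted p values there belonged to Ndufv3 (-0.43), Ndufb3 (-0.47), Ndufb7 (-0.42) and Ndufa10 (0.40). Complexes II and III had 0 of 11 called (mean 0.06, adjusted p = 0.691), with Cyc1 at 0.43, Uqcrc2 at 0.28, Uqcr11 at -0.24 and Uqcrh at 0.13. For complex IV, 1 of 15 was higher, Cox6a2 (mean 0.21, adjusted p = 0.651). Complex V had 0 of 16 called (mean 0.04, adjusted p = 0.879), with Atp5k at -0.50, Atpif1 at 0.60, Atp5g2 at 0.34 and Atp5g3 at -0.24. The citric acid cycle had 0 of 20 called (mean -0.04, adjusted p = 0.651), with Dlat at -0.41, Pdhb at 0.40, Idh3b at 0.31 and Idh3a at -0.38. The calls of Hspa9 (without FtMT-Adip 1), Cisd1 (without WT 1, WT 2 or FtMT-Adip 1) and Fdxr (without any 1 of the 4 arrays) were lost, with log2 changes over the left-out arrays of 0.71 to 1.09, -0.99 to -0.50 and 0.49 to 0.64. In the authors' normalized values none of these 3 genes was called, and the change of Hspa9 was 0.30. Without WT 1, complex IV had 3 higher members.

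Targets of the stress-response transcription factor ATF4 rose as a list, which does not show by itself which stress raised them. Of 30 tested genes 14 were higher and 3 lower (18 and 3 when adjusted over the list alone), with a mean log2 change of 0.72 (adjusted p = 8.12e-08 by camera, adjusted p = 0.296 with an estimated correlation). Besides Gdf15, Trib3 and Ddit3, the hormone gene Fgf21 was 4.28-fold higher (log2 change 2.10, SE 0.153, adjusted p = 0.000441). The lower members were Gpt2 (-1.35), Vldlr (-0.97) and Phgdh (-0.82), which act in alanine metabolism, lipoprotein uptake and serine synthesis. Without FtMT-Adip 1 the lower members numbered 1. Mitochondrial chaperones and proteases also rose as a list, with 4 of 15 higher and 0 lower (6 and 0 over the list alone, mean 0.29, adjusted p = 0.00929, adjusted p = 0.713 with an estimated correlation). They were Hspa9 (0.90, SE 0.161), the protease gene Lonp1 (0.85, SE 0.164) and the chaperonin genes Hspd1 (0.79, SE 0.146) and Hspe1 (0.70, SE 0.157). That list lost its call without WT 2 (mean 0.20, adjusted p = 0.108) and without FtMT-Adip 2 (mean 0.26, adjusted p = 0.0502), and its higher members numbered 2 without WT 1, 2 without WT 2 and 1 without FtMT-Adip 1. Single calls ended for Lonp1 without WT 2 or FtMT-Adip 1 (0.70 to 0.99 over the left-out arrays), for Hspd1 without WT 1 (0.73 to 0.86), for Hspa9 without FtMT-Adip 1 (0.71 to 1.09) and for Hspe1 without any 1 array (0.63 to 0.78). In the authors' normalized values Hspa9 (0.30), Hspd1 and Hspe1 were not called.

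Other stress lists were higher as well. Immediate early genes had 4 of 22 higher and 0 lower (5 over the list alone, mean 0.44, adjusted p = 9.44e-05, adjusted p = 0.510 with an estimated correlation), namely Atf3 (log2 change 1.92, SE 0.193, also in the ATF4 list), Egr2 (1.42, SE 0.177), Gadd45g (1.10, SE 0.169) and Fos (1.09, SE 0.211). Heat shock and ER chaperones had 4 of 22 higher and 0 lower (6 over the list alone, mean 0.36, adjusted p = 0.000117, adjusted p = 0.486 with an estimated correlation), namely Hspa1a (1.20, SE 0.137), Creld2 (1.00, SE 0.188), Sdf2l1 (0.94, SE 0.171) and Hsph1 (0.85, SE 0.176). The number of higher chaperones was 2 without WT 2 and 1 without FtMT-Adip 1. The antioxidant list went both ways, with 3 of 41 higher and 3 lower (3 and 6 over the list alone, mean 0.02, adjusted p = 0.921). Srxn1, which reduces oxidised peroxiredoxins and is listed as NPN3, was 2.99-fold higher (log2 change 1.58, SE 0.212, adjusted p = 0.00361), and Sqstm1 was also higher (0.78, SE 0.167). Mgst3, a microsomal glutathione transferase gene, was 2.85-fold lower (-1.51, SE 0.175, adjusted p = 0.00205), and the extracellular superoxide dismutase gene Sod3 was lower (-0.99, SE 0.197). The lower count was 1 without WT 1 and 1 without FtMT-Adip 1, and the higher count 1 without WT 2. Without FtMT-Adip 1 the calls of Fos, Creld2, Sdf2l1, Hsph1, Sod3 and Sqstm1 were lost. The calls of Fos, Creld2, Hsph1 and Sqstm1 were also lost without WT 2, those of Sdf2l1 and Sod3 without WT 1, and that of Sqstm1 without FtMT-Adip 2. Over the left-out arrays their log2 changes were 0.86 to 1.32 for Fos, 0.81 to 1.19 for Creld2, 0.74 to 1.14 for Sdf2l1, 0.69 to 1.01 for Hsph1, -1.25 to -0.73 for Sod3 and 0.58 to 0.97 for Sqstm1. In the authors' normalized values Gadd45g, Fos, Creld2, Sdf2l1, Hsph1 and Sqstm1 were not called.

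Adipocyte genes fell. Of 38 tested identity genes 17 were lower and 1 higher (21 and 1 over the list alone), with a mean log2 change of -0.64 (adjusted p = 6.79e-12, adjusted p = 0.571 with an estimated correlation). Adipoq, the adiponectin gene listed as ACDC (ILMN_2738082), was 2.55-fold lower (log2 change -1.35, SE 0.155, adjusted p = 0.00195). Besides Cfd, the retinol-binding protein gene Rbp4 was 3.78-fold lower (-1.92, SE 0.151, adjusted p = 0.00057) and the carbonic anhydrase gene Car3 3.35-fold lower (-1.74, SE 0.130, adjusted p = 0.000451). Lep, which encodes leptin, was 2.85-fold lower (-1.51, SE 0.328, adjusted p = 0.0263), with a change of -0.90 without FtMT-Adip 1 and a call that ended without WT 2 or without a variance trend. Pparg, the central regulator of adipocyte differentiation, stood at 0.07 (SE 0.177, adjusted p = 0.872) by its brightest probe. Of its 3 tested probes, 2 had the opposite sign. The higher member was Plin2, which coats lipid droplets (0.82). The count of lower members was 10 without WT 1 and 10 without FtMT-Adip 1, and Plin2 was not called without FtMT-Adip 1. Macrophage markers moved in the opposite direction in the same arrays, with a mean of 1.12.

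Acute phase and secreted adipose proteins fell as a list, with 16 of 25 lower and 3 higher (16 and 4 over the list alone, mean -0.88, median -1.29, adjusted p = 8.12e-08, adjusted p = 0.296 with an estimated correlation). The list shares 5 tested genes with adipocyte identity. Beyond Mest, Cfd and Serpina3c, the haptoglobin gene Hp was 4.50-fold lower, Sfrp5 4.71-fold and Saa3 4.25-fold. Its higher members were Gdf15, Fgf21 and Itih4 (0.57). Cholesterol synthesis genes fell as a list, with 4 of 21 lower and 0 higher (9 over the list alone, mean -0.38, adjusted p = 9.99e-06, adjusted p = 0.597 with an estimated correlation). They were Nsdhl (-1.28, SE 0.179), Insig1 (-0.72, SE 0.145), Fdps (-0.67, SE 0.153, with another probe of opposite sign) and Sc5d (-0.64, SE 0.152). The lower members numbered 1 without WT 2 and 1 without FtMT-Adip 1. Insig1 and Fdps lost their calls without any 1 array (-0.76 to -0.68 and -0.73 to -0.61), and Sc5d without WT 1, WT 2 or FtMT-Adip 1 (-0.79 to -0.49). Insig1 and Sc5d were also not called in the authors' normalized values.

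Lipogenesis and glucose use had 3 of 26 genes lower and 1 higher (3 and 2 over the list alone, mean -0.11, adjusted p = 0.361). Pnpla3, a lipid-remodelling enzyme gene listed as ADPN, was 4.76-fold lower (log2 change -2.25, SE 0.313, adjusted p = 0.00427), the desaturase gene Scd1 2.06-fold lower (-1.05, SE 0.124) and the citrate carrier gene Slc25a1 2.04-fold lower (-1.03, SE 0.193). The pyruvate kinase gene Pkm was higher (0.90, SE 0.148, 1 of 2 tested probes called). Fatty acid oxidation had 2 of 25 higher and 1 lower (2 and 4 over the list alone, mean -0.12, adjusted p = 0.120), namely Acot2 (0.65, adjusted p = 0.0338), the coactivator gene Ppargc1b (0.61, SE 0.149) and Echs1 (-0.77, SE 0.177). Both lists passed, downward, without WT 2 (adjusted p = 0.0128 and 0.0110) and without FtMT-Adip 2 (adjusted p = 0.0188 and 0.0233). The lipogenesis mean was 0.06 without WT 1 and 0.07 without FtMT-Adip 1. Fatty acid oxidation had 0 higher and 2 lower without WT 2, 1 and 3 without FtMT-Adip 2, 2 and 0 without WT 1, and 0 and 0 without FtMT-Adip 1. The higher count of the lipogenesis list was 3 without WT 1 and 3 without FtMT-Adip 1. Calls were lost for Slc25a1 without WT 2 or FtMT-Adip 1 (-1.24 to -0.81), Echs1 without WT 1 or FtMT-Adip 1 (-0.94 to -0.60), Acot2 without WT 2 or FtMT-Adip 1 (0.44 to 0.86) and Ppargc1b without any 1 array (0.55 to 0.67). In the authors' normalized values Scd1, Slc25a1, Pkm, Echs1 (-0.17), Acot2 and Ppargc1b were not called. Acot2 was above background on 1 of the 2 WT arrays.

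Thermogenic genes depended on WT 1. With all 4 arrays 1 of 18 was higher, Fabp3, and 2 were lower, Clstn3 (log2 change -0.97, SE 0.199) and Otop1 (-0.76, SE 0.176), with 3 higher and 2 lower over the list alone (mean 0.30, adjusted p = 0.483). Ucp1, the uncoupling protein of brown and beige fat, had a change of -1.18 (SE 0.688, adjusted p = 0.376), with raw signals of 498.1 in WT 1, 108.1 in WT 2, 110.2 in FtMT-Adip 1 and 132 in FtMT-Adip 2. Cidea (839.1 against 225.5) and Cox7a1 (1392 against 441.4) were likewise brighter in WT 1 than in WT 2. Without WT 1 the list passed upward (6 higher, 0 lower, mean 0.81, adjusted p = 4.27e-06), and without WT 2 the mean was -0.21, with 11 of 18 genes negative (adjusted p = 0.0843). The number of lower genes was 4 without WT 2, 0 without FtMT-Adip 1 and 1 without FtMT-Adip 2. Clstn3 lost its call without WT 1 or FtMT-Adip 1 (-1.22 to -0.71), and Otop1 without WT 1, FtMT-Adip 1 or FtMT-Adip 2 (-0.97 to -0.54). Otop1 was also not called in the authors' normalized values.

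**Figure D2:**
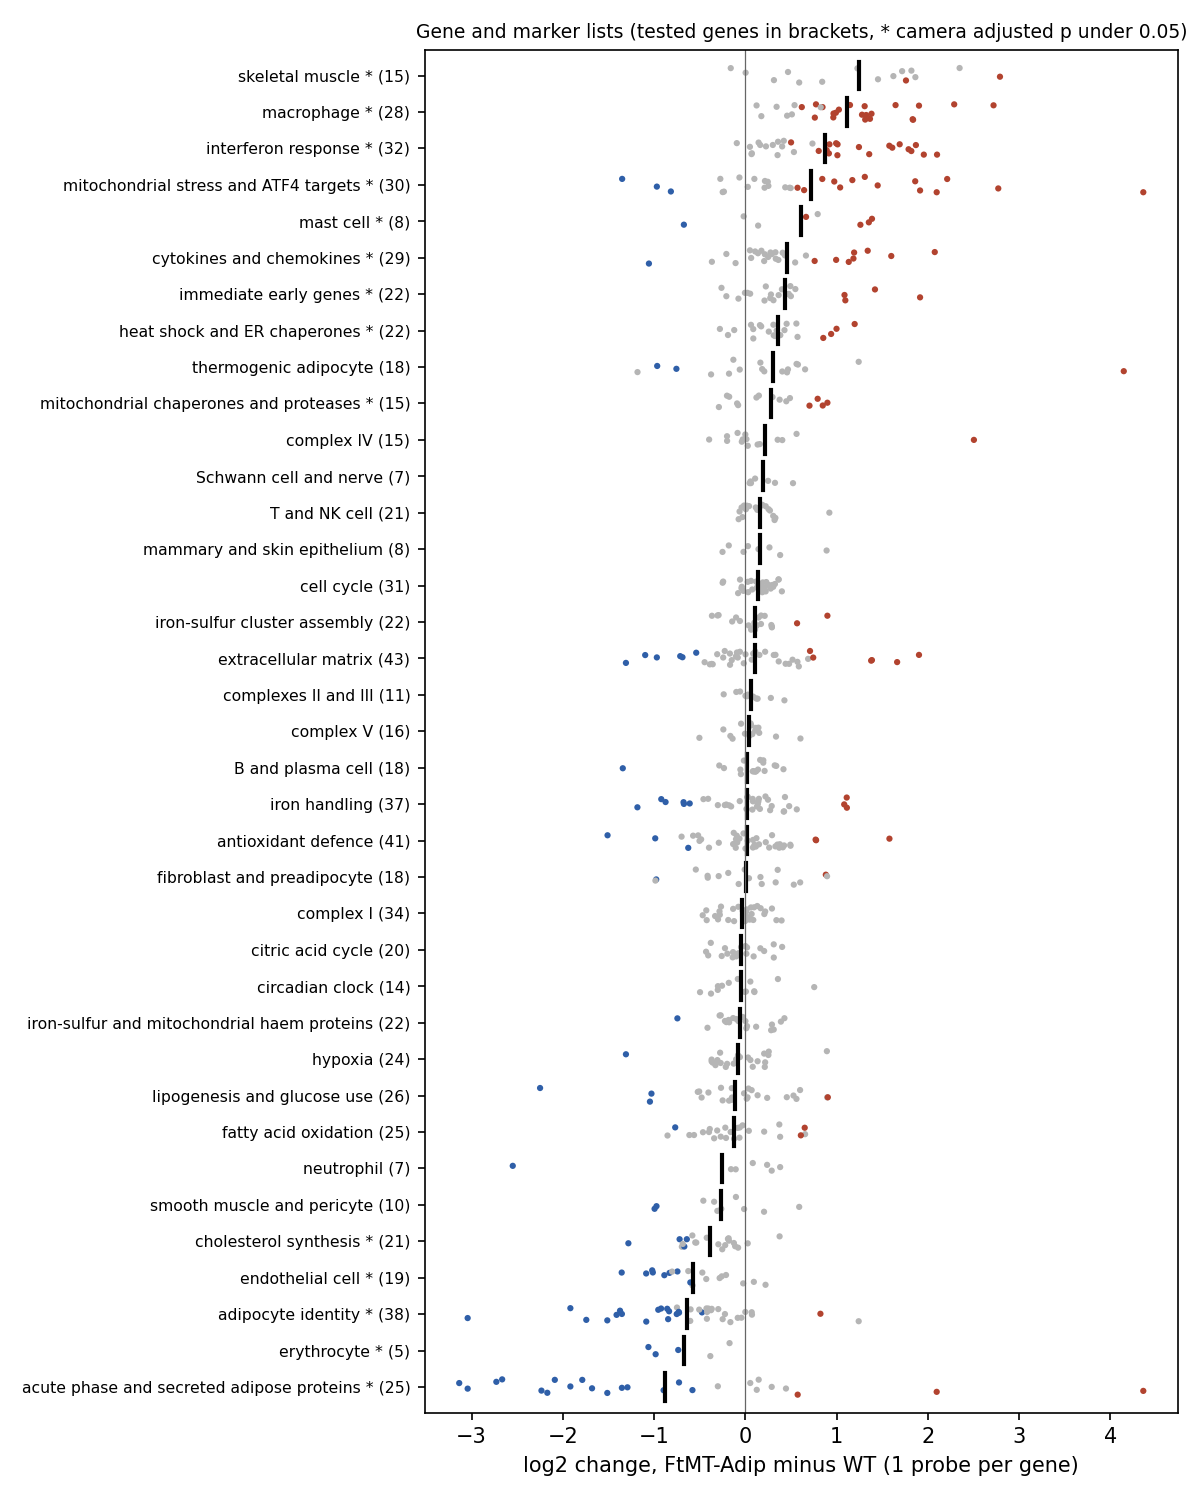
Each point is a tested gene of a fixed list, placed by its log2 change (FtMT-Adip minus WT, 2 arrays per group); red and blue points were called higher and lower, grey points were not called, and the black bar marks the list mean. The macrophage (mean 1.12) and interferon (0.87) lists lie to the right and the adipocyte (-0.64) and secreted protein (-0.88) lists to the left, while complex I (-0.03) lies near 0.

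Macrophage markers rose, with 21 of 28 tested genes higher and 0 lower (25 over the list alone, mean log2 change 1.12, adjusted p = 2.38e-21, adjusted p = 0.448 with an estimated correlation). After Gpnmb and Trem2, the elastase gene Mmp12 was 3.74-fold higher (1.90, SE 0.272, adjusted p = 0.00467) and the Fc receptor chain gene Fcer1g 3.58-fold higher (1.84, SE 0.160, adjusted p = 0.000657). The interferon response rose in 18 of 32 genes and fell in 0 (21 over the list alone, mean 0.87, adjusted p = 5.8e-18, adjusted p = 0.296 with an estimated correlation). The antiviral genes Rsad2 (4.29-fold, adjusted p = 0.000441), Oasl1 (3.88-fold, adjusted p = 0.000441), Ifit3 (3.65-fold, adjusted p = 0.000795) and Oas2 (3.53-fold, adjusted p = 0.00119) led it. Its median was 0.85, and 0.81 with dim genes at their bounds. Cytokines and chemokines had 8 of 29 higher and 1 lower (10 and 1 over the list alone, mean 0.46, adjusted p = 2.81e-06, adjusted p = 0.408 with an estimated correlation). Among them the chemokine gene Ccl4 was 4.22-fold higher (2.08, SE 0.222, adjusted p = 0.00142), the interleukin-1 receptor antagonist gene Il1rn 3.03-fold (SE of log2 0.215), Ccl9 2.53-fold (1.34, SE 0.165) and Ccl8 2.29-fold (1.19, SE 0.201). Cxcl14 was lower (-1.06), and not called without WT 1 or FtMT-Adip 1. Ccl9 was not called in the authors' normalized values.

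Mast cell markers rose as a list, with 4 of 8 higher and 1 lower (5 and 1 over the list alone, mean 0.61, adjusted p = 0.00764, adjusted p = 0.713 with an estimated correlation). The protease genes Cma1 (1.39, SE 0.269), Cpa3 (1.35, SE 0.215) and Mcpt4 (1.26, SE 0.213) were higher and the receptor gene Kit was lower (-0.67, SE 0.165). The list was not called without WT 2 (mean 0.46, adjusted p = 0.0677, 2 higher), nor was Cma1 (0.98 to 1.80 over the left-out arrays), and Kit, of the 4 leave-outs, was called only without FtMT-Adip 2 (-0.80 to -0.55). Kit was also not called in the authors' normalized values. T and NK cell markers had 0 of 21 called (mean 0.16, adjusted p = 0.160), with Il7r at 0.92, Cd4 at 0.32, Icos at 0.33 and Cd7 at 0.25. They passed upward without WT 2 (mean 0.39, adjusted p = 2.79e-05, 2 higher), without FtMT-Adip 1 (mean 0.27, adjusted p = 0.00807) and in the matrix that the authors normalized. Without WT 1 the T and NK cell mean was -0.07, with 17 of 21 genes negative. B and plasma cell markers had 1 of 18 lower, the immunoglobulin gene Ighm (-1.34, SE 0.147; list mean 0.02, adjusted p = 0.823). Neutrophil markers had 1 of 7 lower, S100a8, and the mean of -0.26 and the median of 0.08 differed in sign (adjusted p = 0.921).

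Endothelial markers fell, with 8 of 19 lower and 0 higher (13 over the list alone, mean log2 change -0.57, adjusted p = 7.77e-08, adjusted p = 0.448 with an estimated correlation). The tight junction gene Cldn5 was 2.56-fold lower (-1.36, SE 0.178, adjusted p = 0.00336), the transcription factor gene Sox18 2.12-fold (-1.09, SE 0.152), the cadherin gene Cdh5 2.03-fold (-1.02, SE 0.163) and Gpihbp1, which carries lipoprotein lipase across capillaries, 2.02-fold (-1.01, SE 0.201). The lower members numbered 4 without WT 2 and 3 without FtMT-Adip 1, and Gpihbp1 was not called without WT 1 or FtMT-Adip 1 (-1.29 to -0.74). Smooth muscle and pericyte markers had 2 of 10 lower, Rgs5 (-0.99, SE 0.164) and Mylk (-0.97, SE 0.155), with 3 lower and 1 higher over the list alone (mean -0.27, adjusted p = 0.0563). This list passed without WT 1 (adjusted p = 0.0481) and without FtMT-Adip 1 (adjusted p = 0.0280). Erythrocyte markers fell, with 3 of 5 lower and 0 higher (4 over the list alone, mean -0.67, adjusted p = 5.59e-05, adjusted p = 0.408 with an estimated correlation). These were Hba-a1 (-1.06, SE 0.164), Alas2 (-0.98, SE 0.159) and Hbb-b1 (-0.74, SE 0.124), of which the globin genes have near-identical copies. Sox18, Rgs5, Mylk, Alas2 and Hbb-b1 were not called in the authors' normalized values.

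Fibroblast and preadipocyte markers had 1 of 18 higher, Ly6a (0.88, SE 0.155), and 1 lower, Dpt (-0.98, SE 0.149), with 4 each over the list alone, and a mean of 0.01 whose sign differs from the downward camera test (adjusted p = 0.974). This list had 3 higher without FtMT-Adip 2 (mean 0.15), 0 higher and 2 lower without FtMT-Adip 1 (mean -0.14), and 2 lower without WT 2. Extracellular matrix genes had 6 of 43 higher and 6 lower (7 and 7 over the list alone, mean 0.10, adjusted p = 0.921). The higher ones included Mmp12, the osteopontin gene Spp1 (1.66, SE 0.396), the collagenase gene Mmp13 (1.39, SE 0.153, with another probe of opposite sign) and Timp1 (1.38, SE 0.157). The lower ones included the cross-linking enzyme gene Lox (-1.31, SE 0.165), Ccn2 (-1.10) and the basement membrane collagen genes Col4a2 (-0.97) and Col4a1 (-0.71). The higher count was 3 without WT 1 and the lower count 3 without FtMT-Adip 1. Spp1 had a change of 0.88 without FtMT-Adip 1 and was not called without WT 1 or WT 2, nor without a variance trend or without background correction, and Ly6a was not called without FtMT-Adip 1 (0.71 to 1.05 over the left-out arrays) nor in the authors' normalized values (0.26). Hypoxia genes had 1 of 24 lower, Lox (mean -0.08, adjusted p = 0.284).

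Cell cycle genes had 0 of 31 called (mean 0.13, adjusted p = 0.152), with Ccne1 at -0.25, Mcm6 at 0.36, Tk1 at 0.40 and Ccnd1 at 0.31, but passed upward without WT 2 (mean 0.38, adjusted p = 8.14e-07) and without FtMT-Adip 2 (mean 0.22, adjusted p = 0.0263). Without WT 1 the cell cycle mean was -0.11, with 22 of 31 genes negative, so its direction depends on the WT arrays. Clock genes had 0 of 14 called (1 higher and 1 lower over the list alone, mean -0.05, adjusted p = 0.587), with Nfil3 at 0.76, Cry2 at -0.50, Ciart at 0.36 and Nr1d1 at -0.38. Mammary and skin epithelium had 0 of 8 called (mean 0.16, adjusted p = 0.621), with Ltf at 0.38, Krt8 at 0.89, Cldn7 at -0.18 and Trps1 at -0.25. For Ltf both WT arrays were below background, and the bound was 1.14-fold, which carries no error and does not show a difference. Schwann cell and nerve markers had 0 of 7 called (mean 0.20, adjusted p = 0.185), with Cnp at 0.52, Mag at 0.33 and Mbp at 0.25, and passed without WT 1 (mean 0.30, adjusted p = 0.0342).

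Skeletal muscle markers were higher as a list, with 2 of 15 higher and 0 lower (11 over the list alone, mean log2 change 1.24, adjusted p = 3.72e-05, adjusted p = 0.733 with an estimated correlation). The called members were Atp2a1 and the skeletal actin gene Acta1 (1.76, SE 0.367, adjusted p = 0.0224). Most of this signal lay in FtMT-Adip 1. The troponin gene Tnnc2 read 128.8 and 144.4 in WT, 1461 in FtMT-Adip 1 and 192.9 in FtMT-Adip 2. The list mean was 0.39 without FtMT-Adip 1 (2 higher) and 2.10 without FtMT-Adip 2 (12 higher), and 0 members were called without WT 1 or without WT 2. Acta1 had a change of 1.05 without FtMT-Adip 1 and was not called without WT 1 or WT 2.

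**Figure D3:**
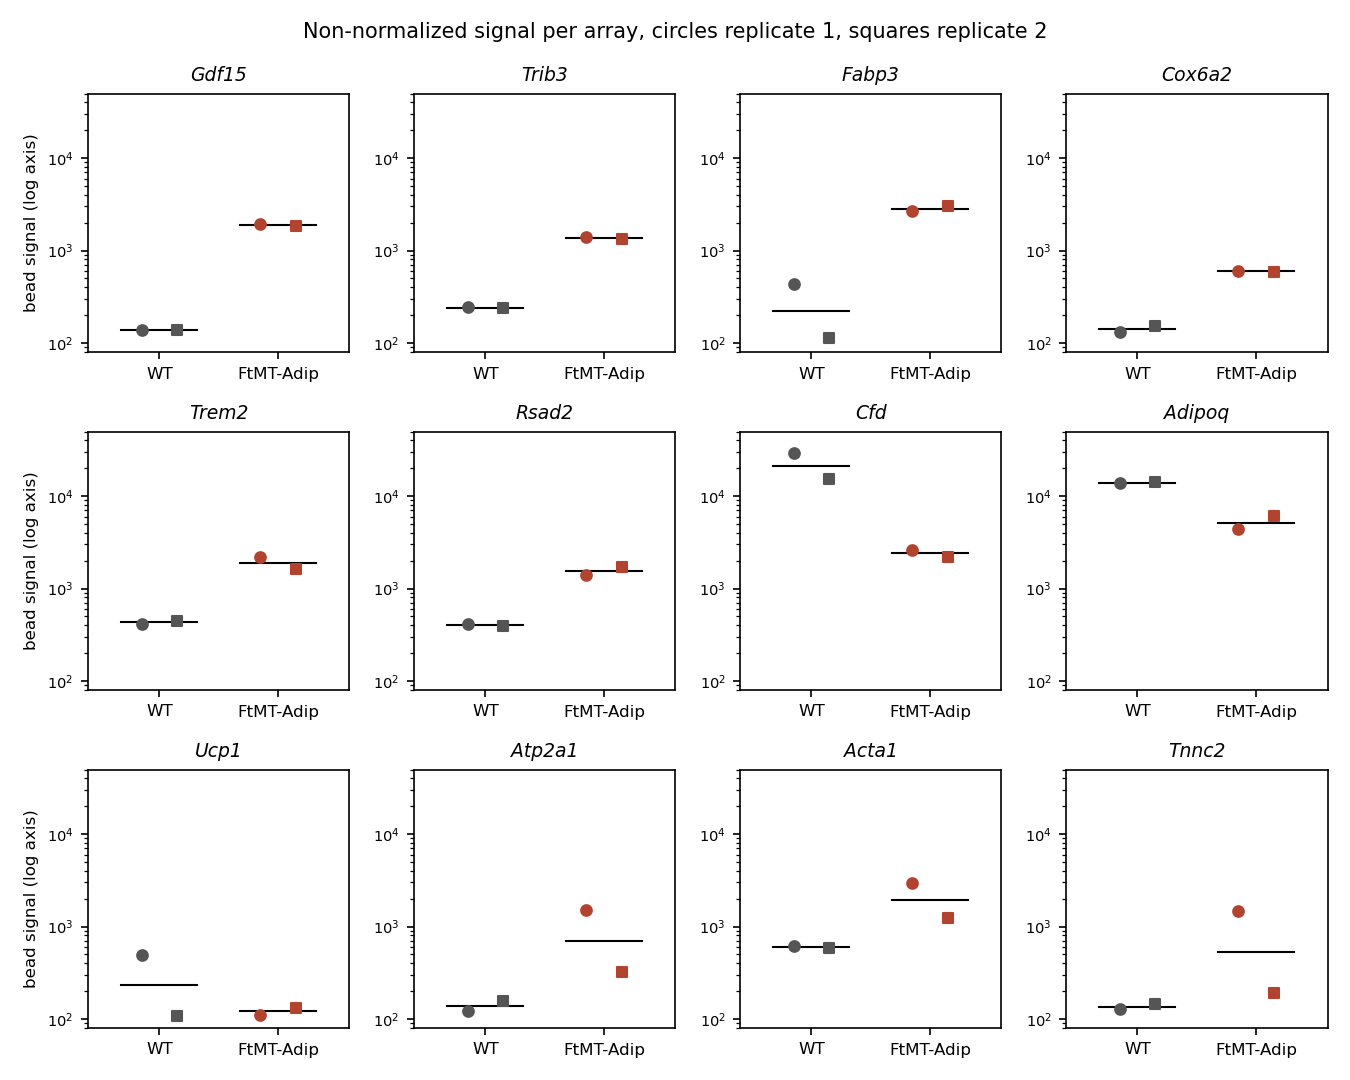
Non-normalized bead signal (log axis, arbitrary units) of 12 genes on each array, with circles for replicate 1, squares for replicate 2 and a line at the geometric mean of each group (n = 2). Gdf15, Trib3 and Cox6a2 are alike within a group, Ucp1 and Fabp3 differ between the WT arrays (498.1 and 108.1 for Ucp1), and the muscle genes Atp2a1, Acta1 and Tnnc2 are brightest in FtMT-Adip 1.

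In total 14 of the 37 lists passed the camera test with a preset correlation of 0.01, 9 higher and 5 lower. With an estimated correlation 0 passed, the smallest adjusted p being 0.296. Correlation does not account for every loss, since the estimate lay below the preset for ATF4 targets (-0.034), secreted proteins (-0.027) and the interferon response (-0.007). For the other called lists it lay above the preset, up to 0.85 for skeletal muscle markers. By fry, which asks whether a list moves on balance one way, 4 passed (ATF4 targets, secreted proteins, the interferon response, and smooth muscle and pericyte).

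The authors' deposited table gives a ratio of group means and a p-value for each probe. A p under 0.05 is given there for 3052 probes, 1658 with a ratio over 1 and 1394 with a ratio under 1, and 0 remained after Benjamini-Hochberg adjustment of those values. For Gdf15 the authors' deposited table lists a ratio of 21.9 and p = 0.125, for Trib3 5.83 and p = 0.00264, and for Cfd 0.147 and p = 0.056.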

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

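The neqc normalization with empirical detection probabilities and the detection filter from a background mirrored at the mode of each array were chosen after the data were seen. The count of 1548 called probes fell to 695 in the authors' normalized values and 695 in the identical values of the series table, of which 616 were shared, 79 were called there alone, and 4 of the 1548 had the other sign. The median within-group SD was 0.253 on the log2 scale in the authors' values and 0.120 in the main ones; the cause was not tested. Leaving out 1 array gave 652 to 1626 probes, lowest without FtMT-Adip 1 and highest without FtMT-Adip 2, where fewer arrays also leave a single one in a group. The other settings without a block gave 1365 to 1652. Among called probes, 41.0% to 48.0% were higher in FtMT-Adip in every setting, and 0 of the 91 called named genes and 0 of the 14 called lists changed sign, while the means of some lists that were not called did (thermogenic, cell cycle, T and NK cell, lipogenesis). Of these 91 genes, 51 kept their call under every alternative in which they were tested (Fabp3 and Rnase2a were not tested in all). Besides the authors' values and left-out arrays, a change of background correction, normalization, filter, variance trend or block ended the call of Atp2a1, Lep, Spp1, Fdps, Fdxr, Cisd1, Hspe1, Sqstm1, Echs1, Acot2, Ppargc1b, Otop1, Sc5d and Kit. The 14 lists became 0 with an estimated correlation and 4 by fry, 3 of them shared. Mitochondrial chaperones and proteases also lost their call in the authors' values, and erythrocyte markers with stricter detection. With the replicate number as a block, 1225 probes were called (1182 shared) and 14 lists. Deviations of same-numbered arrays correlated at -0.0793 across probes, which shows no shared factor but cannot exclude one. A slide block was not run because no slide is given. Probes near the receptor background have little signal to show a change.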

Other observations

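The genes and gene lists of the next paragraph, the tests on Fabp3 and Cox6a2 and the check without Atf3 were chosen only after the results were seen. All other tests below were fixed before the values they measure were seen.

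Several receptor genes were lower in FtMT-Adip, 9 of the 13 tested in a group of lipid and metabolite receptors, with 0 higher. The short-chain fatty acid receptor gene Ffar2 was 4.19-fold lower, the lactate receptor gene Hcar1 was lower by a log2 change of -1.81, the succinate receptor gene Sucnr1 was 3.49-fold lower and the long-chain fatty acid receptor gene Ffar4 3.19-fold. They were picked after their values were seen, so no list test is given for them or for the groups below. Of 41 lysosomal genes 11 were higher and 1 lower, Acp5 (mean log2 change 0.42), led by Cd68 (3.57-fold), Ctsz (2.69-fold) and Lgmn (2.52-fold), of which Cd68 is also a macrophage marker here. Of 76 cytosolic ribosomal protein genes 5 were higher and 1 lower (mean 0.29), while 0 of 71 mitochondrial ribosomal protein genes were called (mean -0.01). Aminoacyl-tRNA synthetase genes, which include ATF4 targets, had 0 of 18 called (mean 0.22). Among 17 imprinted genes, Mest, Nnat and Peg3 (log2 change -2.15) were lower and H19 (0.95) was higher.

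Adipocyte genes were lower and macrophage genes higher in FtMT-Adip. A lower share of adipocytes in the tissue piece, with nothing else changed, would raise the markers of every other cell type alike. The endothelial median, however, lay 1.61 below the macrophage median on the log2 scale (difference -1.61, permutation p = 1e-05, the smallest the permutations can give). The fibroblast median lay 0.99 below the macrophage median (-0.99, p = 1e-05 by permutation). Cells that change in number together with adipocytes are not covered by this comparison. Lymph node tissue in the transgenic samples would bring B and T cells, but their medians differed from the macrophage median by -0.90 (permutation p = 0.0009) and -0.87 (permutation p = 0.0004); these 4 two-sided comparisons permute genes, which are not independent replicates, and the largest adjusted p was 0.0009. As a hypothesis, macrophage accumulation together with lower adipocyte expression in the transgenic genotype may underlie the pattern, and a change in the adipocyte share beside such an accumulation stays open.

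ATF4 target genes were higher in FtMT-Adip. Handling stress or RNA quality differing between the groups remains a possible explanation. Immediate early genes (mean 0.44) and the heat shock and ER chaperone list (0.36) rose with the ATF4 list (0.72). Both passed camera with a preset correlation, as was predicted beforehand for this explanation. These lists do not measure RNA quality itself, and no RNA quality value was among the values used here. The chaperone list mixes heat shock genes (Hspa1a and Hsph1 called) with ER genes (Creld2 and Sdf2l1 called). The ER genes may rise with the ATF4 response itself, so their rise is not separate evidence for handling. That limit does not cover the heat shock genes Hspa1a (log2 change 1.20) and Hsph1 (0.85). Hspa1a kept its call in all 15 alternative settings and Hsph1 in 11 of 15. With an estimated correlation none of the 3 lists passed (adjusted p = 0.510, 0.486 and 0.296). That test has little power at 2 arrays per group and does not decide the question, so the handling explanation stays open. Atf3 belongs to both the ATF4 and the immediate early list, and without it (a check added after the results were seen) the means were 0.37 for immediate early genes and 0.68 for the ATF4 list, and both passed camera with a preset correlation. The transgene itself, which acts in mitochondria, stays open as the biological explanation, and it was not tested apart from the group.

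Fabp3 and Cox6a2, genes of muscle-type energy metabolism, were higher in FtMT-Adip. Skeletal muscle fibres in the tissue piece would make them follow the muscle markers, whose median difference between FtMT-Adip 1 and FtMT-Adip 2 was 2.00 on the log2 scale over 15 genes (quartiles 0.60 to 2.58), whereas Fabp3 differed by -0.06 and Cox6a2 by 0.13, with an SD of at most 0.0924 within FtMT-Adip (the WT arrays, with an SD of 1.77 for Fabp3, do not enter this comparison). More thermogenic adipocytes in the tissue piece cannot be told apart from a rise of these genes alone, because the median of the 17 other thermogenic genes was 0.18 with quartiles of -0.18 to 0.47 and did not pass camera, and the WT arrays differed in Ucp1. An effect of the genotype on these genes may remain, as an untested explanation.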
